A study of Boswellia sacra with 4 samples.

How the data were processed

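Stem RNA of Boswellia sacra, the frankincense tree, was sequenced from unwounded stem and from stem collected 30 min after wounding, with 2 biological replicates in each group per the labels. Libraries were made from total RNA depleted of ribosomal RNA and read on an Ion Torrent instrument, per the labels' protocols. ERCC spike-in RNA was added per the same protocols, and 0 rows of the table carry an ERCC name.

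The authors deposited FPKM values, 1 per contig and group, in a table of 10570 contigs. The table was made with Cuffdiff, per the submitters' processing notes. Its version, the aligner and the assembly settings are not given in the sources used here. Contig names begin with TRINITY, per the file itself, and the contigs lie on a single artificial sequence with spacers, so positions have no meaning in a genome and only contig lengths are given. Lengths had a median of 282 bp and ran from 201 to 5131 bp, so several contigs can belong to 1 gene and short contigs of a gene family can share reads. Protein names come from the best database hit or the description in the table and were not checked against a genome. Prefixes that name no protein were removed from them after the names were seen, which lowers the count of 1 row per protein name.

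The p-values and q-values are those the authors deposited, 1 of each per contig. The authors' test gave a result for 8652 contigs. It was not run for 1783 contigs marked as having too few data and for 135 marked as having too much. In 2 rows the cells were shifted by 2 columns and were read from their shifted places. The deposited log2 ratio column holds cells damaged by a spreadsheet, so folds were computed here from the FPKM values as log2 of wounded over control. No fold is given where a group is listed at 0. No per-replicate values were used, so there is no replicate spread beside a value, and no test across replicates was run for the main results. The depth per sample is not given in the table.

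A contig was called at a q-value under 0.05. The share of calls that were higher has an exact Clopper-Pearson interval at 95%, which covers counting error over contigs that are not independent replicates. The 44 gene lists were fixed before the data were examined, as were the tests, the alternatives and the rule for named genes. Lists were matched on the best hit and the whole description of each contig, so a contig can count in a list that its printed name does not point to. Species names were removed first, except for the list of microbial or animal names. The removal was a correction made after the annotation was seen, because a list for cork matched the name of the cork oak. A two-sided Fisher exact test compared calls in each list with calls among the other tested annotated contigs, for each direction, with Benjamini-Hochberg adjustment over lists and directions. Lists with fewer than 5 tested members were counted only. The median log2 fold change of each list, with a pseudocount of 1 and at least 1 FPKM in a group, was set against 10000 random lists of the same size matched in 10 bins of mean FPKM. On simulated data with 1 of 40 lists raised, over 7652 contigs, the list test called the raised list and 0 others. Only higher calls were simulated, and the raised list had a call rate above that of every real list tested, of which the highest was 40.0%. The simulation therefore does not show that the test finds shifts of the size seen here. SciPy 1.17.1, pandas 2.3.3 and NumPy 2.4.6 were used under Python 3.11.15.

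Named genes were, first, the 10 higher and 10 lower calls of largest fold among those with at least 1 FPKM in both groups and a named protein. Further ones were up to 3 called members per direction of each list by FPKM, up to 2 members of a list without calls, and up to 5 calls listed at 0 in each group. Alternatives covered the threshold, a fold requirement, a filter on low values, the adjustment, 1 row per protein name, the pseudocount, centring and the background.

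After the data were examined, the low FPKM values were multiplied by an effective contig length, from a fragment length of 200 with an SD of 80 and a minimum of 28. The products fell on sums of 3 steps in each group. Each product up to 1500 was split into whole numbers of the 3 steps, taken as reads of 3 read sets, within the rounding of the deposited value and a relative tolerance of 2e-06. A split was found for 84.8% of such values in control and 85.8% in wounded stem, against 5.22% and 5.36% after multiplying the values by a constant. On simulated reads for 10570 contigs the search found 3 steps in each group, and every split with a single solution returned the simulated reads. The unit of the values stays FPKM. limma 3.58.1 with voom was run on the recovered reads of contigs with at least 10 reads as an added alternative. With 200 contigs simulated as raised 8-fold, it recovered 90.5% of them with 3 false calls among 4431 contigs. Where the first 2 control read sets were summed, it recovered 80.0% with 5 false calls among 4404 contigs. The simulated read sets shared 1 level per contig. Most real pairs within a group had Spearman correlations of only 0.01 to 0.18, so these rates need not hold for the real reads.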

Results

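The series asks how the stem of Boswellia sacra, a tree tapped for frankincense resin, responds to wounding of the kind made during resin extraction. Gene expression was compared between control stem and stem taken 30 min after wounding, with 2 labelled replicates in each group. The values are the authors' FPKM per contig and group, and no replicate spread can be set beside them.

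Contigs named as transcription factors and signalling proteins known from early stress responses were among those with higher values 30 min after wounding. A contig of 258 bp named CRT/DRE-binding factor 3 (XLOC_007362) went from 2254 to 15780 FPKM, a log2 fold change of 2.81. It is named after a family that switches on cold and drought genes, and the name was not checked. A contig named MYC2-like (XLOC_009235), after the main transcription factor of jasmonate signalling, went from 4.39 to 27.1 FPKM. A mitogen-activated protein kinase (XLOC_009493) was listed at 0 in control and at 44.3 FPKM in wounded stem. Expansin (XLOC_008533), a protein that loosens cell walls, went the other way, from 79.5 to 5.60 FPKM, a log2 fold change of -3.83. The largest folds among calls with a named protein and at least 1 FPKM in both groups had names outside these families. A contig named protein tar1 (XLOC_001143) went from 1.37 to 85.3 FPKM, a log2 fold change of 5.96. A contig named bm21 (XLOC_003821) went from 2628 to 19.9 FPKM, a log2 fold change of -7.04.

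Of 8652 tested contigs, 1451 were called in the authors' deposited table, 1193 higher and 258 lower in wounded stem, and 7201 did not pass. The share of calls that were higher was 82.2% (exact 95% interval 80.2 to 84.2%). Most calls compared a value with a 0: 1087 of the higher calls were listed at 0 in control, and 168 of the lower calls were listed at 0 in wounded stem. Among contigs above 0 in both groups, 106 were called higher and 90 lower, a share of 54.1% (exact 95% interval 46.8 to 61.2%). The values of each group resolved into 3 read sets where the labels list 2 replicates. In 4472 contigs with recovered reads, the authors' deposited table calls 933, each against a 0, while limma voom on the reads called 179 higher and 103 lower (63.5% higher), with 91 shared, and 51 higher and 1 lower (98.1% higher) with the first 2 control read sets summed, with 1 shared. Both fits enter 3 wounded read sets, and the first also 3 control sets, where the labels list 2 samples in each group. The first 2 control sets had a Spearman correlation of 0.92 across contigs. The median log2 fold changes of the fits were 0.95 and 0.94, so their counts and shares by direction rest on a scaling that did not centre these contigs.

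No list passed the enrichment test in either direction. The smallest adjusted p was 0.207 by the Fisher exact test with Benjamini-Hochberg adjustment, for higher calls among AP2/ERF transcription factors and for lower calls among contigs with microbial or animal names. Over all biological and cell type lists, 302 contigs were called, and 313 when adjusted over the list alone. Where no separate count is given below, the count adjusted over the list alone was the same.

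Among 41 tested AP2/ERF transcription factors, a family that includes the ethylene response factors, 13 rose, 0 fell and 28 did not pass, and 14 rose when adjusted over the list alone. Of the 13, 11 were listed at 0 in control. The contig named ERF037 (XLOC_002555) was listed at 0 in control and at 44.8 FPKM in wounded stem, and ERF4 (XLOC_005679) went from 3.46 to 24.5 FPKM, a log2 fold change of 2.82. The list's median log2 fold change was 1.57, above all 10000 random lists matched on mean FPKM, and across the alternatives it ran from 1.15 without the filter on low values to 2.65 with a pseudocount of 0.01. The medians of the calcium signalling list, 1.22, and the heat shock list, 1.09, lay at percentiles 99.7 and 99.1 of such lists; across the alternatives they ran from 1.04 to 1.88 and from 0.66 to 1.76. Further lists lay high, with heat stress transcription factors at percentile 98.7, jasmonate signalling at 97.95, gibberellin at 95.8 and MYB at 95.2. Lists that lay low included jasmonate biosynthesis at percentile 15.7, ethylene at 28.1, auxin at 7.94, pathogenesis-related proteins at 5.62 and ribosomal proteins at 4.32. These percentiles are not adjusted over the 40 lists that have one. Of 14 tested WRKY factors 0 rose and 0 fell, and a contig named WRKY 17 (XLOC_006876) had 18.6 FPKM in control and 5.75 in wounded stem. The WRKY list had a median log2 fold change of 0.54, at percentile 39.2. In the MYB list 3 of 17 contigs rose (4 adjusted over the list alone) and 1 fell. Of those 3, 1 is named tom1-like (XLOC_003050), which is not the name of a MYB factor. Among NAC factors 2 of 12 rose. Of 4 C2H2 zinc finger factors 2 rose, among them ZAT10 (XLOC_007916), listed at 0 in control and at 12.7 FPKM in wounded stem.

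Jasmonate is the hormone most closely tied to wounding. Of 27 tested contigs of jasmonate biosynthesis 6 rose, all 6 listed at 0 in control, and 0 fell. They included an allene oxide cyclase domain protein (XLOC_008498) at 15.01 FPKM, a 13S-lipoxygenase (XLOC_000086) at 9.02 and 12-oxophytodienoate reductase 3 (XLOC_009791) at 8.13 in wounded stem. Of 19 jasmonate signalling contigs 4 rose, among them the repressor TIFY 9 (XLOC_005493), listed at 0 in control and at 14.6 FPKM in wounded stem. Of 39 ethylene contigs 9 rose, including ethylene insensitive 3-like 1 (XLOC_001472) at 12.5 FPKM against 0 in control. In the abscisic acid list 7 of 42 rose and 0 fell, and in the gibberellin list 8 of 33 rose (9 adjusted over the list alone) and 1 fell, the receptor GID1B (XLOC_007204), from 253 to 74.7 FPKM. In the auxin list 8 of 39 rose and 2 fell. The ARG2 contig (XLOC_004613), named as induced by auxin and placed in the abscisic acid list as well, went from 1.33 to 37.4 FPKM, a log2 fold change of 4.81, and SAUR72 (XLOC_007481) went from 19.99 to 2.42 FPKM.

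Calcium carries early wound signals between cells. Of 59 calcium signalling contigs 14 rose, 2 fell and 43 did not pass, and 17 rose when adjusted over the list alone. The calcium-binding protein CML27 (XLOC_001116) went from 26.0 to 111 FPKM, while cyclic nucleotide-gated ion channel 2 (XLOC_008543) went from 23.2 to 5.41 FPKM. Of 5 MAP kinase cascade contigs 2 rose, and of 44 receptor-like kinases 11 rose, each of the 11 listed at 0 in control, and 13 rose when adjusted over the list alone. In the ubiquitin ligase list 23 of 103 rose (27 adjusted over the list alone) and 2 fell. U-box protein 18 (XLOC_008837) was listed at 0 in control and at 25.1 FPKM in wounded stem, and ATL6 (XLOC_009917) at 17.5 FPKM against 0. Of 40 contigs for reactive oxygen production and scavenging 8 rose, and of 21 glutathione S-transferases 4 rose.

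Heat shock proteins, which keep other proteins folded under stress, had 194 tested contigs, of which 35 rose, 2 fell and 157 did not pass, and 36 rose when adjusted over the list alone. A class II small heat shock protein (XLOC_007707) went from 6.04 to 76.0 FPKM, a log2 fold change of 3.65, and a class I protein (XLOC_002108) from 3.55 to 25.7 FPKM. Of 14 heat stress transcription factors 4 rose, all listed at 0 in control. Among pathogenesis-related proteins 2 of 45 rose and 1 fell, the osmotin-like protein (XLOC_008949), from 15.2 to 2.06 FPKM, and 0 rose when adjusted over the list alone.

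Frankincense resin is rich in terpenes, made from isoprenoid precursors. Of 7 contigs of the plastid MEP pathway 2 rose, both named deoxyxylulose phosphate synthase, the entry enzyme of that pathway. Of 10 mevalonate pathway contigs 2 rose, including hydroxymethylglutaryl-CoA reductase (XLOC_006661), listed at 0 in control and at 6.68 FPKM in wounded stem. Of 4 prenyl diphosphate synthases 1 rose and 3 did not pass: a geranyl diphosphate synthase (XLOC_006262) was listed at 0 in control and at 25.0 FPKM in wounded stem. Of 6 tested terpene synthases 0 rose and 0 fell, and a germacrene D synthase-like contig (XLOC_000607) had 112 FPKM in control and 82.2 in wounded stem. The median log2 fold change of the terpene synthase list was 0.95, at percentile 76.3 of matched random lists. Of 10 triterpenoid and sterol contigs 1 rose, beta-amyrin synthase (XLOC_006676), at 10.5 FPKM against 0 in control. In the phenylpropanoid and lignin list 11 of 54 rose and 1 fell, and caffeoylshikimate esterase (XLOC_005117) went from 9.36 to 65.3 FPKM. In the flavonoid list 6 of 55 rose and 1 fell, flavonoid 3'-hydroxylase (XLOC_001221), from 21.8 to 3.66 FPKM.

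In the cell wall list 24 of 144 contigs rose (25 adjusted over the list alone) and 5 fell. A contig named as a pectin methylesterase inhibitor (XLOC_001954) went from 296 to 1278 FPKM, and a polygalacturonase contig (XLOC_001037) from 17.7 to 71.4 FPKM. Another contig with the same inhibitor name (XLOC_003696) went the other way, from 1291 FPKM in control to a listed 0 in wounded stem. A pectinesterase contig (XLOC_001274) was also lower, going from 116 to 19.4 FPKM. Plasmodesmata callose-binding protein 3 (XLOC_000775), which sits at the channels between cells, went from 56.4 to 4.61 FPKM, a log2 fold change of -3.61. The 2-alkenal reductase (XLOC_003915), which removes reactive aldehydes, went from 3086 to 187 FPKM, a log2 fold change of -4.04. An exordium-like protein (XLOC_006530) went from 120 to 3111 FPKM, a log2 fold change of 4.70. In the starch and sucrose list 13 of 47 rose (14 adjusted over the list alone) and 3 fell, among them an acid invertase (XLOC_001362), from 100.3 to 20.3 FPKM. These counts include both pectin methylesterase inhibitor contigs above and contigs named receptor-like (XLOC_004292, XLOC_003812) or magnesium transporter 2 (XLOC_004141). Several of them count in the cell wall list as well, so the counts are not of sugar enzymes alone. Of 43 cytochrome P450 contigs 5 rose, of 40 ABC transporters 4 rose, 2 of them with enterobacterial names, and of 8 protease inhibitors 1 rose. Of 9 clock contigs 3 rose (5 adjusted over the list alone). In the histone and cell cycle list 1 of 21 rose, histone H2B (XLOC_007742), from 2.55 to 24.9 FPKM, and 1 fell, histone H2AX (XLOC_002165), from 590.0 to 130.0 FPKM.

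**Figure D1:**
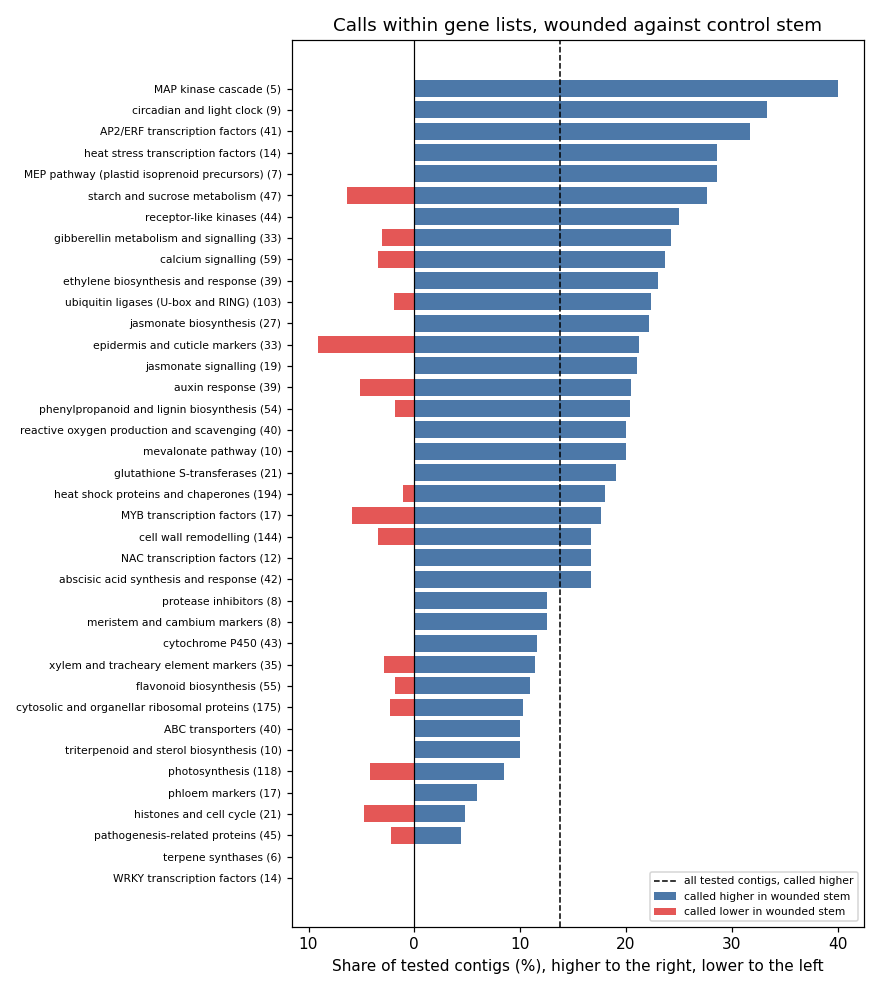
Share of tested contigs (%) called higher (bars to the right) or lower (bars to the left) in wounded against control stem for each gene list, with the number of tested contigs in brackets. The dashed line is the share of all tested contigs called higher, 13.8%. AP2/ERF factors, with 13 of 41 higher, lie above it, and WRKY factors and terpene synthases have no call.

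Markers of cell types were called in both directions. Of 35 xylem marker contigs 4 rose and 1 fell, of 17 phloem markers 1 rose, of 33 epidermis and cuticle markers 7 rose and 3 fell, of 4 cork markers 1 rose and of 8 meristem markers 1 rose. Adjusted over the list alone, 10 epidermis and cuticle markers and 0 meristem markers rose. In the photosynthesis list, which marks green cortex, 10 of 118 rose and 5 fell, and 8 rose and 4 fell when adjusted over the list alone. A chlorophyll a-b binding contig (XLOC_001559) went from 165 to 38.4 FPKM, and the ribulose bisphosphate carboxylase contig (XLOC_009025) from 45.8 to 193 FPKM. In the ribosomal protein list 18 of 175 rose and 4 fell, and 16 rose and 3 fell when adjusted over the list alone. Contigs named after enterobacteria were called as well, with 47 of 392 higher and 6 lower. In the wider list of microbial or animal names 66 of 527 were higher and 26 lower, and its median log2 fold change of 0.05 lay below all 10000 matched random lists, and reached 0.15 without the filter on low values. Of 106 contigs named after transposons 13 rose (12 adjusted over the list alone) and 3 fell.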

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

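The test of contig length and abundance was set before its result was seen; the other tests in this part were chosen after. The authors' test was not run on 135 contigs marked as having too much data, which no comparison above uses. Of these, 97 were listed at 0 in both groups, 10 only in control and 28 only in wounded stem. The highest values were 8791 FPKM in wounded stem, for XLOC_009373, and 46849 FPKM in control, for XLOC_009967. A 0 under this mark can be a skipped estimate, so these values are not read as a difference between the groups.

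More tested contigs were listed at 0 in control, 1621, than in wounded stem, 195. Recovered reads were used to ask whether a lower total of control reads could be the whole cause. The largest control read set, with 45010 recovered reads, had a read in 57.4% of 5360 contigs. A wounded read set of 40156 reads had one in 78.02%, a gap of 20.6 percentage points. Within these contigs the number of reads does not account for the gap. The totals leave out contigs of high value, and the 5360 include contigs listed at 0 in control, so the depth of whole libraries stays open. Control values that rest on fewer independent libraries than read sets are a candidate explanation for the 0 values of the group. They would not account for the gap above, which lies between single read sets. The first 2 control read sets had a Spearman correlation across contigs of 0.92 and the highest wounded pair 0.18, a difference of 0.74. These correlations bear on redundancy of the sets and do not test whether it caused the 0 values. Those 2 control sets had a chi-square per degree of freedom of 1.74, against 2.92 to 11.9 for the other pairs; repeat runs of a single library can exceed counting noise too, so whether they are that is open. The other pairs within a group had correlations of 0.01 to 0.18, and pairs between groups 0.01 to 0.14. Control read set 3 had 0.02 and 0.01 with control read sets 1 and 2. With wounded read sets 1, 2 and 3 it had 0.01, 0.14 and 0.05, so it was no closer to its own group. Simulated read sets that differ by counting only, under the same limit on totals, gave 0.94 for the first 2 control sets and 0.67 to 0.80 for the other pairs within a group. Which read set belongs to which labelled sample is open.

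Contigs named after enterobacteria were called higher in 11.99% of cases (exact 95% interval 8.94 to 15.6%), against 13.9% of the other contigs. The interval holds the share of the other contigs. Names come from best hits or descriptions, and the origin of these contigs was not tested. A wounding response therefore cannot be told apart from other sources of their calls, and bacterial load may differ between the stems. The wider list of microbial or animal names had 66 higher and 26 lower calls among 527 contigs, with a median log2 fold change of 0.05, below all matched random lists. For the contigs of other names, called higher in 13.9% of cases, a wounding response and a difference between the libraries cannot be told apart either, since the read sets cannot be tied to labelled samples. Of the 940 higher calls against 0 with recovered reads, 928 had reads in at least 2 wounded sets. limma voom shared 91 of its 282 calls with the authors' 933 in the setting with 3 read sets per group, and 1 of its 52 with the first 2 control sets summed.

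AP2/ERF factors had 13 higher calls among 41 tested contigs, though the list did not pass adjustment (adjusted p 0.207 by the Fisher exact test). Contig length and abundance do not account for the number: 99.99% of random lists matched on both had fewer higher calls, and their median was 5. An early response of this family to wounding is a hypothesis that these data leave open, since the list was picked as the most extreme of 40 for higher calls and the libraries differ as described above.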

How the results depend on the processing

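No paired analysis was possible because the table holds 1 value per group and no replicate columns, and for the same reason leaving out replicates and the other planned fits on counts were not run. Against 1451 calls, an adjusted p of 0.01 gave 434, and 1 row per protein name gave 910. Bonferroni gave 0, since the smallest p in the authors' deposited table, 5e-05, is shared by 243 contigs and becomes 0.43, while 2196 contigs had an unadjusted p under 0.05. The requirement of a 2-fold change, the filter at 1 FPKM and a recomputed Benjamini-Hochberg adjustment left 1451, 1444 and 1451. The fold requirement could remove no call. The 1255 calls listed at 0 in a group were passed without a fold, and the others had a log2 fold of at least 1.53 in size. The recomputed adjustment used the same p-values. Settings chosen after seeing the data gave 196 calls above 0 in both groups, 1398 without enterobacterial names, and, of 1075 calls with recovered reads, 1038 with reads in at least 2 of 3 read sets of the higher group. limma voom on the recovered reads gave 282 calls with 3 read sets per group and 52 with the first 2 control read sets summed. It tested only 4472 contigs, of which the authors' deposited table calls 933, each against a 0. Its median log2 fold changes were 0.95 and 0.94, against -0.02 and -0.11 in simulated data, so its scaling did not centre these contigs, and its counts rest on that scaling. The share of calls that were higher moved from 82.2% to 54.1% among contigs above 0 in both groups. It was 63.5% and 98.1% under the 2 voom settings, over their smaller set of contigs. Calls in any biological or cell type list fell from 302 to 115 at an adjusted p of 0.01. No list passed enrichment under any background, with smallest adjusted p between 0.083 and 0.207. All 180 alternatives for folds of named genes kept their direction, which these alternatives could not change. A pseudocount keeps the sign of a fold. Centring used a median of -0.10, while the smallest called log2 fold was 1.53 in size. Of 160 alternatives for list medians, 3 changed sign or reached 0. The cause was not tested for the moved counts except where stated. The 940 higher calls against 0 with recovered reads had a median of 16 wounded reads.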

Other observations

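The groups in this part were chosen after their values were seen, and no enrichment test was run on them. Of 32 tested contigs named as CCCH zinc finger proteins, a family that binds RNA, 7 were called higher and 1 lower. The highest, XLOC_010050, went from 37.0 to 259 FPKM, and XLOC_005176, named CCCH protein 29, was listed at 0 in control and at 45.0 FPKM in wounded stem. Of 30 galactinol and raffinose synthase contigs, which make sugars that accumulate under stress, 6 were called higher and 0 lower, all 6 listed at 0 in control.

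Contigs of the S-adenosylmethionine cycle, which supplies methyl groups and the precursor of ethylene, were called in both directions. S-adenosylmethionine synthase (XLOC_010019) went from 7.60 to 60.7 FPKM, while adenosylhomocysteinase (XLOC_004761) was at 35.7 FPKM in control and listed at 0 in wounded stem. A contig named after the nematode resistance protein HSPRO2 (XLOC_005078) was listed at 0 in control and at 84.7 FPKM in wounded stem.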
